A study of Mus musculus with 2 samples.

How the data were processed

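DNA methylation was compared between hypothalami of female FVB/NJ mice raised in small litters (SL, 4 pups, an early postnatal overnutrition model) and in control litters (C, 9 pups), all collected at postnatal day 180. Per the series design text, equal amounts of DNA from 5 hypothalami of a group made a pool, with 2 pools (10 hypothalami) per group. From each pool 500 ng was digested with SmaI and then with XmaI, ligated to adaptors and amplified by PCR, and 2 ug of product was dyed for hybridisation. Both enzymes recognise CCCGGG: SmaI leaves blunt ends only where the site is unmethylated, and XmaI then opens the remaining sites with overhangs that accept the adaptor, so a fragment gives more signal when both of its ends are methylated. The assay measures relative amounts of such fragments, not a methylation percentage.

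There were 2 cohybridisations, each of SL against C. On array 1 SL carried Cy5 and C carried Cy3, and on array 2 the dyes were exchanged, per the labels. Which pool went onto which array is not given in the sources used here. The arrays were treated as 2 independent pairs of pools; if both held the same pools, the spread between them would be technical only. Both arrays lay on 1 slide and were scanned together, so no batch could be tested.

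The authors extracted the spot intensity of each channel with Agilent Feature Extraction; the submitters' processing notes name version 9.1.3.1 and the file headers name version 10.5.1.1. Per the file headers, the processed signal of each channel is an intensity after background subtraction and dye normalisation, with a multiplicative detrend fitted on array 1 and none on array 2. The authors also deposited a log10 ratio of Cy5 over Cy3 per spot, and a value table whose entries equal that log10 ratio with array 2 turned, that is, SL over C on both arrays. The differences between the table and the turned ratio stayed below 0.005 on the log10 scale, so scale and direction were settled, and no further centring of the table was found; its column medians were 0 and -0.00128.

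Each array held 96645 spots, of which 6110 were control spots and 90535 carried 90526 distinct genomic probes of 45 to 60 bases, placed by the array design on mouse build mm8. Of the genomic spots 44 had an outlier flag on either array and were left out. A probe was kept when it was well above background in at least 1 channel on each array, which left 86472 probes. The log2 ratio of the processed signals was turned to SL over C and centred on the median of each array, with no loess or quantile step, as suits an assay in which most probes carry signal. Neighbouring probes with starts at most 500 bp apart formed a region, and a region's value on an array was the mean over its probes; 22534 groups of probes arose, 3987 with a single probe were left out, and 18547 regions with 82485 probes were tested. The planned grouping by consecutive CCCGGG sites needed probe or genome sequence and was replaced by this distance rule, which had been fixed as its fallback.

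Regions were tested with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), and single probes likewise. Standard errors (SE) are the moderated ones of limma, and n is 2 arrays throughout. The same fit on Cy5 over Cy3 without turning array 2 gave the dye contrast, in which a difference between SL and C cancels only where it is equal on both arrays; a difference on 1 array alone enters both contrasts. Regions past 1.5-fold in the same direction on both arrays were counted beside regions past 1.5-fold in opposite directions, which is where a dye effect lies after a dye swap. An exact two-sided sign-flip test of 2 arrays cannot give p below 0.5. The number of arrays limits the precision: the median SE of a region's mean log2 ratio was 0.34. The region test was tried on simulated data with the arrays' own spread and 200 of 18547 regions changed, in 10 draws. It recovered 0% of regions changed 1.5-fold, 1% at 2-fold, 52% at 3-fold and 93.4% at 4-fold. Each draw kept a region's values on both arrays and changed only their common sign. Two-sided p without added change was therefore that of the real data, and the 1 call per draw was the observed one. A mean of 4 calls per draw fell outside the changed regions. They may hold real differences, so neither number is a rate of false calls. The simulated fold sizes were reset after a first run to resolve the smaller ones.

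The tests, the filters, the thresholds, the alternatives and the rule for named regions were fixed before the data were examined. The rule named up to 12 regions per direction, ranked by the smaller of the arrays' absolute log2 ratios among regions passing the test with 1 sign on both arrays, and filled each direction by the same ranking from regions past 1.5-fold the same way on both arrays, stated as not having passed. For a region whose probes in a group were not well above background on both arrays, a floored fold is given. On each array the brighter group's centred processed signal was set over the dim group's own signal or a floor, whichever was higher. The floor was the lowest signal among probes well above background in that channel. The floored fold is averaged over the arrays, so it is no bound for each array, and it stays open to dye bias. The same floor was applied to the called region after its signals were seen. Alternatives covered background correction (normexp with offset 50, on median rather than mean spot signals), loess, the deposited ratio and value table, filters on dim and saturated probes, region definition, moderation, thresholds and each array alone. A correction for probe length and a scaling of both arrays to a common spread were added after seeing the data. Figures were drawn with matplotlib 3.10.9.

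The probes carry positions on mm8 and no gene names, and the gene table at hand is on GRCm38, so regions are named by position. The 20 planned gene lists, the split by promoter, exon and intron, and the correction for GC content were not run for this reason, and genes were not analysed here.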

Results

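The study asked whether overnutrition during suckling, produced by raising pups in small litters, goes with a different DNA methylation pattern in the adult hypothalamus, the brain region that governs feeding and energy use. Pooled hypothalamic DNA of SL and C females was cohybridised on 2 arrays with the dyes exchanged. Signal was high relative to background: 95.58% of genomic probes on array 1 were well above background in Cy5 and 95.36% in Cy3, and on array 2 the shares were 95.87% and 94.56%. No genomic probe was saturated. The median signal was 1658 (Cy5) and 1798 (Cy3) on array 1, and 1089 and 1073 on array 2. The 18547 regions had a median of 4 probes and a median length of 542 bp, and the largest held 43 probes. Log2 ratios spread more widely on array 1, with an SD across regions of 0.67, than on array 2, with 0.34.

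The simulation described above gives no rate of chance calls for the test of SL against C. A single region passed this test. It lies at chromosome 5, positions 115821516 to 115821757 (mm8), and its fragment signal was lower in SL, with a measured mean log2 ratio of -2.31 ± 0.34 (SE, n = 2 arrays; limma adjusted p = 0.0355). The ratio was -2.65 on array 1 and -1.98 on array 2, and both of the 2 probes that the filter kept were lower in SL on both arrays. Its signal in SL lay near background: 1 of 2 probes was well above background on array 1 and 0 of 2 on array 2, against 2 of 2 for C on both arrays. The size of the difference is therefore uncertain: with signals below the lowest well-above-background signal raised to it, the log2 ratio was -2.37 on array 1 and -0.67 on array 2. The call was lost in 9 of the alternatives, among them the authors' deposited ratios (-2.31, adjusted p = 0.999 with limma) and normexp background correction (-1.07). Without the filter on dim probes, the region also held probes that were left out here, and its mean was -0.68. Agreement of the 2 kept probes is therefore weak support, as on array 2 both passed the filter through C alone. The region could not be tested where 3 probes, or signal well above background in all 4 channels, were required. No region was called higher in SL by limma. Unadjusted p (limma) was under 0.05 for 384 regions in either direction, where evenly spread p would give 927. Opposite signs on the arrays, dye effects among them, enlarge the SE in this fit. The shortfall therefore does not show that SL and C were alike.

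The other named regions on the lower side were ranked by size and did not pass the test; their adjusted p (limma) lay at 0.577 or above. The region with the lowest mean of the named ones was chromosome 4, positions 47235429 to 47236090, with all 4 probes lower in SL on both arrays and well above background in every channel. Its log2 ratio was -4.02 on array 1 and -0.84 on array 2, a mean of -2.43 ± 0.50 (SE). The arrays differed so much there that it passed the limma test of Cy5 over Cy3 (-1.59, adjusted p = 1.76e-05) and not that of SL over C; it was the 1 named region to do so. A second chromosome 4 region, positions 34442427 to 34443046, also had 4 of 4 probes lower on both arrays, with -2.81 and -0.97 and a mean of -1.89 ± 0.39. On chromosome 12, positions 59354998 to 59355630, the 4 probes averaged -1.95 and -0.74 (mean -1.34 ± 0.36), and on chromosome 15, positions 101926551 to 101927096, the mean of the 3 probes was -1.40 ± 0.36 over the arrays. In these 4 regions array 1 lay farther from zero than array 2. The chromosome 4 regions passed the test under 5 alternatives (the first) and 6 alternatives (the second) and missed it under the others with a test.

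The arrays were closer to each other in a second set of 2-probe regions. At chromosome 7, positions 115821460 to 115821806, the log2 ratio was -0.77 on array 1 and -0.76 on array 2, with signals in C of 2205 and 1509. On chromosome 11 the region at 101286062 to 101286505 had -0.94 and -1.10, although 1 of its probes was at 0.09 on array 1, and the region at 67403934 to 67404416 had -0.90 and -0.75. In the latter region 1 of 2 probes was well above background in C on array 1 and in SL on array 2. A second chromosome 7 region, at 121043902 to 121044336, had -1.29 and -0.85. Chromosome 2 at 115756917 to 115757210 gave -1.48 and -0.79, and chromosome 18 at 64784394 to 64784798 gave -1.64 and -0.76. At chromosome 12, positions 54910635 to 54910900, the measured ratios were -1.46 and -1.04, but SL was not well above background on either array. With SL raised to its floor, the fold averaged over the arrays was 1.32. The floor was 31.97 on array 1 and 33.71 on array 2, against C signals of 61.37 and 30.48. Array 2 therefore gives no lower bound, and a lower SL signal rests on array 1 there.

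On the higher side 4 regions were past 1.5-fold on both arrays, and none of them passed the test. The region at chromosome 13, positions 37521298 to 37521602, had the highest values, 0.86 on array 1 and 1.38 on array 2, a mean of 1.12 ± 0.34 (SE, n = 2, limma adjusted p = 0.642). All 4 probes were higher in SL on both arrays, but C was dim. Its signal was 74.71 on array 1, with 3 of 4 probes well above background, and 36.25 on array 2. Chromosome 7 at 11828714 to 11829246 had 0.81 and 0.72, with 1 of 3 probes at -0.29 on array 2. Chromosome 5 at 139775482 to 139775661 had 0.76 and 0.67 over 2 probes, and chromosome 7 at 34376667 to 34377129 had 0.66 and 0.70, with 1 of 2 probes at -0.27 on array 1. In this last region C was dim too, at 83.11 on array 1, with 1 of 2 probes well above background, and 42.13 on array 2. Of all 16 named regions, 13 had every probe in the region's direction on both arrays. The naming rule favours such agreement, and no share over other regions was computed, so this count is no support for the differences.

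**Figure D1:**
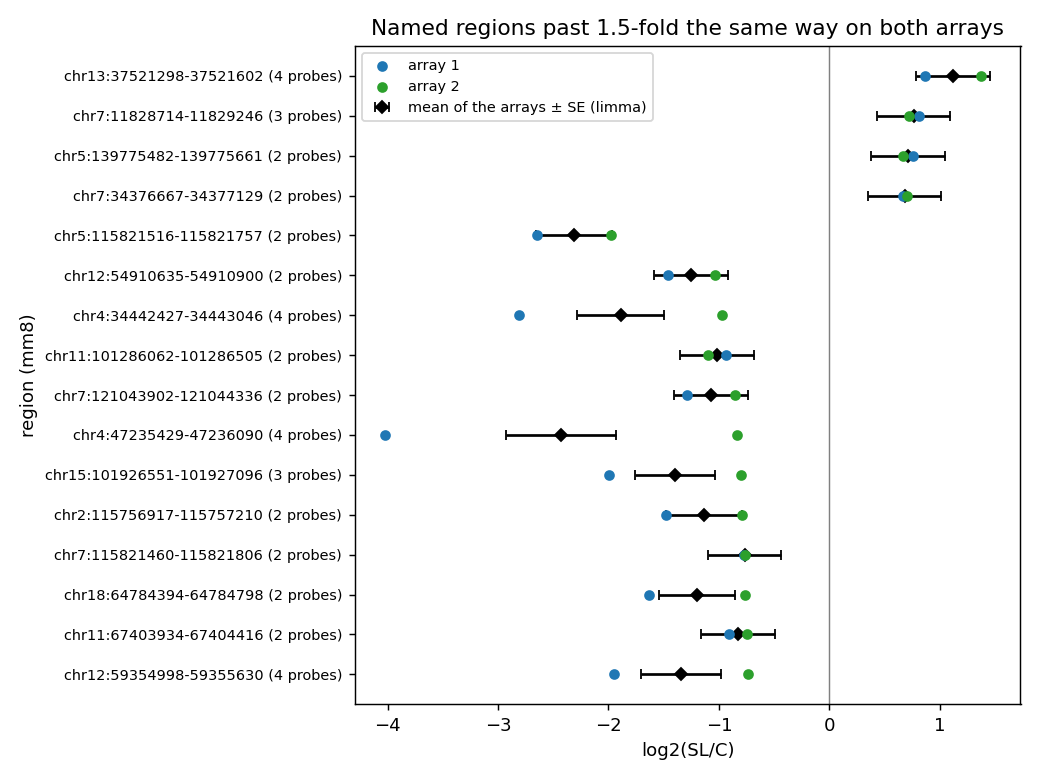
Named regions (mm8 positions, number of probes in brackets) against log2(SL/C), with array 1 in blue, array 2 in green and the 2-array mean with limma's SE in black. Both arrays lie on the same side of zero in all 16 regions by the naming rule, and the gap between the arrays is widest at chromosome 4, positions 47235429 to 47236090 (-4.02 and -0.84).

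Past 1.5-fold in the same direction on both arrays were 42 regions, 38 lower and 4 higher in SL; they were 9 and 1 with normexp background correction, 61 and 1 with loess, and 62 and 1 with the arrays scaled to a common spread, which was added after seeing the data. In opposite directions, where a dye effect lies, were 425 regions, 409 with Cy3 above Cy5 and 16 with Cy5 above Cy3. At 2-fold the counts were 2 regions, both lower in SL, against 165. The count of 42 rests on both arrays being required. Whatever the other array showed, 5043 regions were past 1.5-fold on array 1 and 745 on array 2. The 38 lower regions were spread over 15 chromosomes; 19 of them (50%) had 2 probes, against 17.4% of all regions, and 27 lay in the dimmest quintile of signal. Across regions the log2 ratios of the arrays, both as SL over C, correlated negatively, with Pearson's r = -0.426 and Spearman's rho = -0.353. The 95% interval of r, -0.437 to -0.414, was computed as if regions were independent. They are not independent replicates, so the interval is too narrow, does not measure the spread over pools, and no p is given. Of all regions, 38.1% had the same sign on both arrays.

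**Figure D2:**
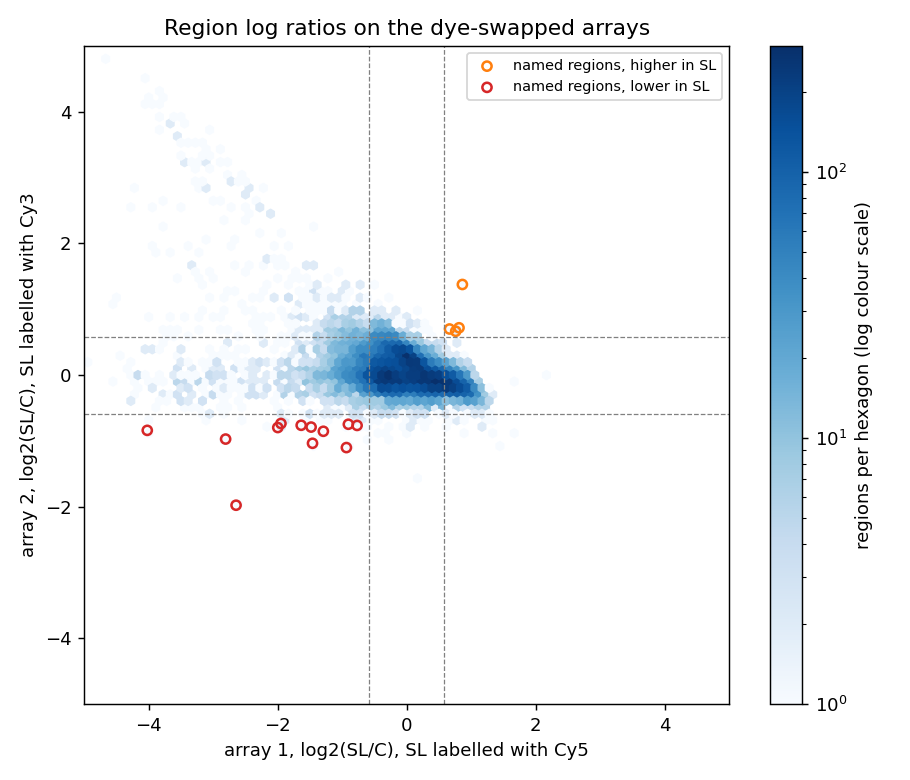
Region log2(SL/C) on array 1 (horizontal) against array 2 (vertical), with darker hexagons holding more regions on a log colour scale, dashed lines at 1.5-fold and circles on the named regions. Regions extend toward the upper left, where Cy3 exceeded Cy5 on both arrays (409 past 1.5-fold), and leftward along zero of array 2, while 42 lie beyond 1.5-fold in the lower left and upper right.

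Set as Cy5 over Cy3, 482 regions passed the limma test, 476 with Cy3 above Cy5 and 6 with Cy5 above Cy3; after a correction for probe length, added after seeing the data, 142 passed. This test does not need both arrays to move: 245 of the 482 were past 1.5-fold in opposite directions on both arrays, and 233 were within 1.5-fold on array 2, so that array 1 carried the call. The region at chromosome 10, positions 6168933 to 6169108, had log2(SL/C) of -4.68 on array 1 and 4.81 on array 2, so Cy3 exceeded Cy5 26.9-fold while the mean of SL over C was 0.07. A chromosome X region, positions 7240619 to 7240876, had -4.09 and 4.47. Of the regions with Cy5 above Cy3, 3 lay close together on chromosome 3: positions 93368485 to 93371415 with a mean log2(Cy5/Cy3) of 1.28 over 16 probes, positions 93375397 to 93378237 with 1.08 over 16 probes, and positions 93367054 to 93367685 with 0.99 over 4 probes (limma adjusted p = 0.00162, 0.0191 and 0.0475). In all 5 of these regions every probe was well above background in all 4 channels. The chromosome 3 regions were very bright, with Cy5 signals of 111500, 81310 and 73650 on array 1, where the median Cy5 signal was 1658. All 5 regions were picked as examples after the values were seen. The direction of SL over C follows the dyes in the labels and the authors' value table; the same 425 regions would count as agreeing differences, and the 42 as disagreeing ones, if the dyes had not been exchanged between the arrays.

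Tested one by one, 357 of 86472 probes passed the limma test, 356 lower and 1 higher in SL. Their ratios came mainly from array 1: the called lower probes had a median log2 ratio of -3.87 on array 1 and -0.13 on array 2. Of all 357, 110 had opposite signs on the arrays and 26 were past 1.5-fold the same way on both. The count was 0 with the authors' deposited ratios. The dye contrast called 2215 probes.

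On array 1, 353 regions were over 4-fold lower in SL and 1 was over 4-fold higher; array 2 had 0 over 4-fold lower and 77 over 4-fold higher. Of the 353, 207 were within 1.5-fold on array 2, whereas 0 regions past 4-fold on array 2 were within 1.5-fold on array 1. The region at chromosome 18, positions 66589814 to 66589894, had a log2 ratio of -4.98 on array 1, where the SL signal was 273.3 and the C signal 8410, and 0.22 on array 2. Chromosome 5 at 116624173 to 116624328 had -4.42 and 0.26, and chromosome 14 at 99203210 to 99203637 had -4.30 and 0.24. Other regions were below zero on array 2 too and dim in SL on array 1. Chromosome 9 at 36509197 to 36510032 had -4.50 and -0.08, with 1 of 4 probes well above background in SL on array 1. Chromosome 4 at 20438603 to 20439286 had -4.30 and -0.44, with 2 of 4 such probes. These differences were seen in 1 of 2 arrays and have no replicate.

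Chromosome medians had the same sign on both arrays for 1 of 20 chromosomes (autosomes and X), chromosome 5, at -0.03 on both. The median of the 367 X regions was above that of the 18177 autosomal regions by 0.21 on array 1 and by 0.00 on array 2, a mean of 0.10 ± 0.15 (SD, n = 2), so the difference was smaller than the spread between the arrays. The lowest autosomal median on array 1 was that of chromosome 13, at -0.18, and it was 0.03 on array 2.

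**Figure D3:**
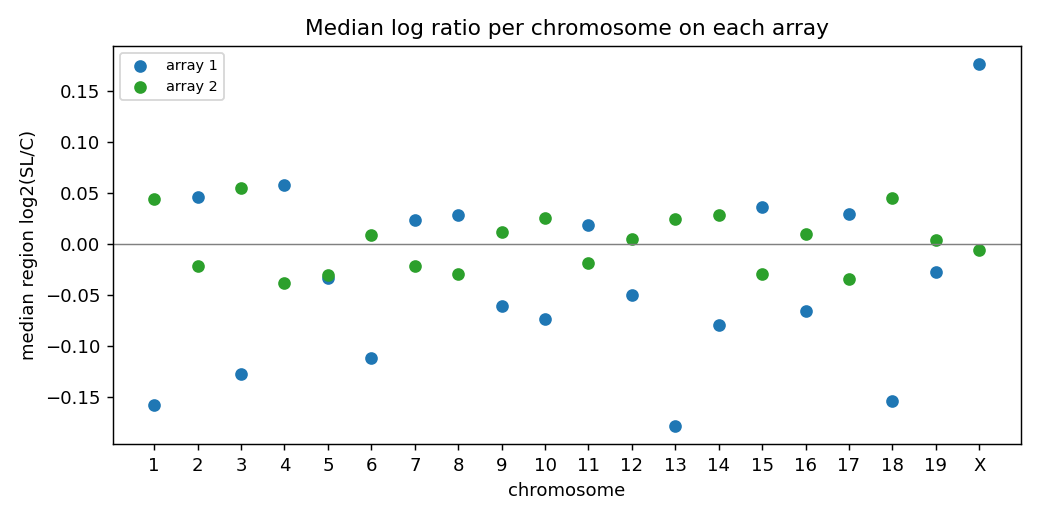
Median region log2(SL/C) of each autosome and of X on array 1 (blue) and array 2 (green). The X chromosome stands at 0.18 on array 1 and -0.01 on array 2, and among the 20 chromosomes drawn, chromosome 5 alone has the same sign on both arrays.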

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

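All settings were planned except the probe length correction and the common spread, which were chosen after the results were seen. Of the probes, 94.56% to 95.87% per channel were well above background, and the called chromosome 5 region (115821516 to 115821757) was dim in SL; it lost its call at an adjusted p under 0.01 and under the 1.2-fold minimum effect (adjusted p 0.0902 with limma), normexp (-1.07), loess (-2.38), the Agilent ratio and the authors' table (both -2.31), no dim filter (-0.68), 1000 bp gaps (-0.85) and the length correction (-2.16). The number of called regions, 1, became 199 with a trend on signal, 133 with all 4 channels above background, 106 with medians over probes, 87 with normexp, 37 with robust moderation, 4 with a common spread, 2 with single-probe regions allowed, and 0 with the minimum effect, an adjusted p under 0.01, loess, the Agilent ratio, the authors' table, no dim filter, 1000 bp gaps, at least 3 probes or the length correction. None of these called a region higher in SL, and larger counts rested on array 1: of the 199, 171 were within 1.5-fold on array 2 (median -0.12), as were 123 of 133, 96 of 106, 82 of 87 and 29 of 37. The estimated prior degrees of freedom of limma moved too, from 17.7 to 7.64 with the Agilent ratio and to infinity with the trend. The 357 called probes became 724 with the trend, 51 with loess, 6 with a common spread, and 0 with the Agilent ratio, the authors' table, no dim filter or the length correction. The 42 regions past 1.5-fold the same way became 270 at the lower fold threshold, 2 at 2-fold, 10 with normexp and 27 with 1000 bp gaps. They became 21 with at least 3 probes and 67 with single probes. With 1 array left out, which leaves no test, 745 to 5043 regions were past 1.5-fold on the other array. The 482 regions of the dye contrast became 142 with the length correction. The correlation of the arrays stayed below 0 under every setting run, at -0.462 with normexp, -0.378 with loess, -0.452 without the dim filter, -0.440 with 1000 bp gaps and -0.476 with the length correction. The cause of these changes was not tested. Among the named regions, 18 values under these settings gained a call, the 8 that lost one were all of the called region, and 0 with a test reversed; leaving out saturated probes moved nothing, as there were none. The settings that need gene names or probe sequence, namely those on gene lists, genomic classes and GC content, were not run.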

Other observations

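The test counting regions whose probes all pass, the tests of dye orientation and of probe length in the Cy3 set, and the background test of the array 1 regions were chosen after the results were seen; the others were set before their outcome was known. Median ratios varied with probe length and signal. On array 1 the median log2(SL/C) of probes was 0.11 at 45 bases and -0.32 at 60 bases, and on array 2 it was 0.12 at 45 bases and between -0.08 and -0.04 in every longer class. From the dimmest to the brightest quintile of probes the median went from -0.14 to 0.40 on array 1 and from 0.25 to -0.12 on array 2. Of 34 chromosome Y probes, 41.2% (SL) and 44.1% (C) on array 1 and 44.1% and 47.1% on array 2 were well above background in these pools of females, against 94.6% to 95.9% of autosomal probes.

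Cy3 exceeded Cy5 by over 2-fold on both arrays in 164 regions, with a median log2(Cy5/Cy3) of -2.38. Bias of single probes could be tested only where it is independent of their neighbours, and as the whole cause it is then argued against. In 88 regions of 3 or more probes every probe was past 2-fold on both arrays, when the largest of 100 shuffles of probes gave 1. A first form of this test counted region means and gave a mean of 88.5 and at most 102 shuffled regions against the 164. By the bound set beforehand this spoke for such a bias, but 1 extreme probe can carry a region mean. Of the probes in the 164 regions 88.2% were past 2-fold themselves. The regions were chosen by their means, and no shuffled share was computed, so this share does not decide between the forms. An average trend of the dye ratio on signal is argued against as the cause by the 89% that stayed after loess. Loess removes only the average trend, so a signal-dependent bias of some probes stays open. Background subtraction or detrending by the scanner software is argued against by the 85.4% that stayed with normexp on raw signals. An average trend on probe length is argued against by the 92.7% that stayed after the length correction, where the median log2(Cy5/Cy3) was still -2.29. That correction too removes only an average, and 44.5% of the set held only 60-base probes, against 6.7% of all regions. Another link to probe length therefore stays open. The set made up 2.13% of regions under 250 bp and 0.2% of those over 750 bp. This length is the span of a region's kept probes, not of a digested fragment, and the shares were not compared at equal probe number. A dye effect on whole fragments and hybridisation of both arrays in the same orientation both give the negative correlation (-0.426), so they cannot be told apart by it. Hybridisation in the same orientation could make this set a shared difference between SL and C, although the labels and the authors' table speak against it. No biological explanation was tested.

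Over 4-fold lower signal in SL on array 1 alone was seen in 207 regions. A background floor is argued against because 92.4% of their probes were well above background in all 4 channels. Their median length was 376 bp, against 542 bp for all regions, and 26.1% held only 60-base probes, so a link to probe or region length stays open. Detrending on array 1 is argued against because 83.6% stayed past 4-fold with normexp on raw signals. An average trend on probe length is argued against because 91.8% stayed after the length correction, which removes only the average and cannot address other links to length. A methylation or sequence difference in the SL pool of array 1, loss of fragments when that pool was digested or amplified, and a Cy5 effect on array 1 stay open and could not be separated with 1 array.

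Past 1.5-fold on both arrays, 38 regions were lower and 4 higher in SL; the counts were 9 and 1 with normexp, 25 and 5 with the length correction, 61 and 1 with loess, and 62 and 1 with a common spread. Array 2 of the main values was shuffled 1000 times within classes of signal and probe number. The shuffles gave a mean of 20.4 lower regions (95% of shuffles 14 to 28) and 51.1 higher ones (39 to 63). The 38 lower regions exceed their range, which argues against chance meeting of the separate spreads within these classes, while the 4 higher ones fall below theirs. The classes left out probe length, and no shuffles were run for the other settings, so chance stays open there. The shuffles gave 149.2 regions with Cy3 above Cy5 against the 409 observed, so part of the departure lies in the dye direction. Dim probes stay open: with probes well above background in all 4 channels, 68.4% of the lower regions (26 of 38) stayed past 1.5-fold, where 7 had no such probe and could not be tested, and 26 of the other 31 are 83.9% (95% exact Clopper-Pearson interval 66.3% to 94.5%). Lower methylation of some fragments in SL may contribute, as a hypothesis that was not tested apart from dim signal.

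Neighbouring regions shared part of their ratios. Over 4755 neighbouring pairs up to 10 kb apart, r of the 2-array mean was 0.218 for SL over C and 0.26 for Cy5 over Cy3, a difference of -0.0422 (95% bootstrap interval -0.0767 to -0.0066). This comparison had been set to test whether a methylation change extended over neighbouring fragments, but it cannot decide that, because the sharing of a dye effect is no reference value for the sharing of SL over C. For SL over C, r was 0.354 up to 2 kb and 0.054 from 2 to 10 kb.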
